A study of Mus musculus with 2 samples.

How the data were processed

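RNA sequencing was carried out on macrophages sorted from mice with acute myeloid leukaemia (AML) driven by MLL-AF9, a fusion oncogene used to model the disease. There were 2 libraries, 1 from bone marrow and 1 from spleen, both collected 15 days after transplantation. Per the labels' protocols, total RNA was extracted from the sorted cells and made into standard Illumina libraries. The surface markers and gates of the sort, the number of mice behind each library, the aligner, the counting program, the genome build and the annotation are not given in the sources used here.

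Each library had a gene table. Per the file headers, the authors deposited for every gene an Entrez gene identifier, a count of uniquely placed reads, a gene length, the percent of the gene's length covered by reads, and an RPKM value, which is the read count scaled to gene length and to the reads of the library. The read counts were whole numbers with a smallest listed value of 1, and they summed to the total stated in each header, 9625763 for bone marrow and 8264712 for spleen. A gene missing from a table therefore had no counted read, and it was given a count of 0. The deposited RPKM values were recomputed from the count, length and total columns and differed by at most 6.7e-06 percent. The median covered share of a listed gene was 83.3 percent in bone marrow and 81.7 percent in spleen in the deposited coverage column. For 7 genes the length differed between the tables, which affects RPKM and not counts. Because only uniquely placed reads were counted, genes with near-identical copies or pseudogenes (haemoglobin genes, Gapdh, the Ear, Stfa, Klra, Ifi200-type, Vpreb and class I H2 families) are uncertain.

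In all, 16428 genes had a read in at least 1 library and 14498 in both. Each library's file held 23 gene symbols that had been turned into dates by a spreadsheet, so genes were joined on the Entrez identifier. Names were taken from a RefSeq table of assembly GRCm38.p6, which matched 16379 identifiers and updated 1164 symbols. The 49 unmatched identifiers kept the deposited symbol. No coordinates are given because no build was named.

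With 1 library per tissue there is no replicate check: no p-value, standard error or adjusted p was computed between tissues, and the differences are between these 2 libraries. Counts were scaled with TMM factors (edgeR 4.0.16, R 4.3.3; 0.977 for bone marrow and 1.02 for spleen) to CPM, which is reads scaled to a common library size. Ratios were taken as bone marrow minus spleen on log2(CPM + 1), which understates the change of low genes. A gene counted as measured with at least 1 CPM and at least 10 reads in at least 1 library, and 12970 genes were. A difference of at least 2-fold on that scale was called higher in 1 library. Folds are ratios of CPM with exact conditional binomial (Clopper-Pearson) 95% intervals, which cover counting error only. PCR reads without molecular identifiers are not independent molecules, and animals were not replicated. A count of 0 allows up to 3 reads, or 0.319 CPM in bone marrow and 0.355 CPM in spleen.

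Before the data were examined, 44 gene lists with 934 distinct symbols were fixed: macrophage and monocyte identity, macrophage programs, markers of other cell types that a sort could hold, and RNA quality. For each list the median log2 ratio of its measured members was compared with 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Lists overlap, so they are not independent. The sex-linked list had 1 measured member and was not compared, leaving 43. In 4 lists a member had no read in 1 library, and setting those members to their bound moved no list's median. The naming rule, also fixed then, took the 12 genes with the largest log2 ratio in each direction among the 9884 genes with at least 10 CPM and 100 reads in a library. It left out 320 genes with provisional, immunoglobulin-segment, T cell receptor-segment or mitochondrial names, judged on the deposited symbol, of which 44 were higher in bone marrow and 62 in spleen. It also took up to 4 members with the largest ratio and up to 2 of the most abundant members of each list, and a set of anchor genes. Not every gene that the rule takes is reported here.

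Alternatives were DESeq2 1.42.0 size factors, library totals alone, pseudocounts of 0.1 and 5, no floor, a floor of 10 CPM, a 4-fold rule, the deposited RPKM, lists without members of other cell types and, chosen after seeing the data, TMM factors and counts that left out markers of other cell types. The procedure was tested on simulated Poisson counts for this comparison (12777 genes past the floor, 50 genes changed by each fold). Of genes raised or lowered by 1.5 on the log2 scale, 96% and 98% passed the 2-fold rule, as did 100% of those changed by 3 in each direction and 0.032% of unchanged genes. The intervals covered the simulated fold in 94% to 100% of changed genes. The simulated counts held no variation between animals, sorts or library preparations, so these rates describe counting error only. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.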

Results

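The series set out to compare the transcriptomes of leukaemia-associated macrophages, the macrophages found in tissue infiltrated by leukaemia, in a mouse model of acute myeloid leukaemia. Leukaemia cells carrying the MLL-AF9 fusion and a green fluorescent label were transplanted into unirradiated C57BL/6J mice at 500000 cells per mouse, and leukaemic mice lived for 25 to 30 days. The stated age of the mice was 6 to 8 weeks for both libraries. At day 15 macrophages were isolated by sorting from both tissues, and 1 RNA-seq library from bone marrow and 1 from spleen are described here. The comparison these libraries allow is between the 2 leukaemic tissues. Macrophages of healthy mice were not analysed here. Reads were found for 15376 genes in the bone marrow library and 15550 genes in the spleen library, at effective depths of 9405947 and 8457857 uniquely placed reads after scaling and with medians of 197 and 167 reads per gene. With 1 library per tissue there were no replicates, so every difference below is a difference between 2 libraries. Intervals of folds cover counting error only, and intervals of list medians describe the spread among the list's genes.

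Granule genes of the granulocyte lineage stood among the most abundant transcripts of the bone marrow library, and antigen presentation genes among those of the spleen library. S100a9, a calcium-binding alarmin of neutrophils and monocytes, was the most abundant transcript in bone marrow at 8965 CPM (its count scaled to library size), against 533 CPM in spleen. Ngp, a neutrophil granule protein, reached 8892 CPM against 452 CPM, and Mpo, the myeloperoxidase of primary granules, 8543 CPM against 103 CPM. In spleen, the translation factor Eef1a1 came first at 8864 CPM and differed little from its 8875 CPM in bone marrow. Cd74, the invariant chain of MHC class II, came second in spleen at 8341 CPM against 945 CPM in bone marrow. Of 12970 measured genes, 1832 (14.1%) were at least 2-fold higher in bone marrow, 1898 (14.6%) were at least 2-fold higher in spleen, and 9240 (71.2%) lay within 2-fold. All genes past 2-fold had a 95% counting interval that excluded equal levels, which follows largely from the size rule and the read floor. Across genes, which are not independent replicates, Pearson's r between the libraries was 0.86 on log2(CPM + 1).

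**Figure D1:**
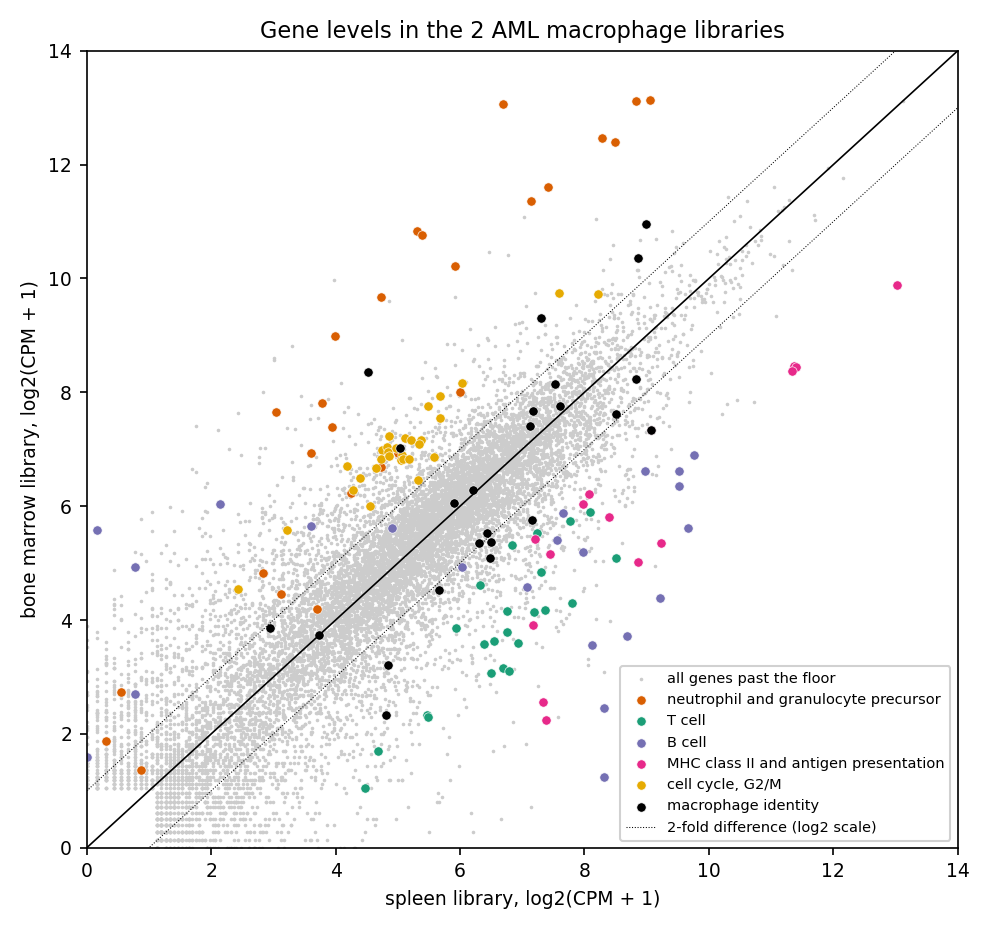
Level of each measured gene in the spleen library (x axis) and the bone marrow library (y axis), both as log2(CPM + 1), with 6 gene lists in colour, the line of equal levels and dotted lines at a 2-fold difference. Granulocyte genes lie above the diagonal and T cell and MHC class II genes below it, while macrophage identity genes lie on both sides.

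The 12 genes with the largest ratios towards bone marrow included genes of granulocyte precursors, eosinophils, basophils, early progenitors and B cell precursors. Mpo was 83.0-fold higher in bone marrow (95% interval 77.7 to 88.9). The neutrophil serine proteases Prtn3 and Elane were 47.4-fold (42.5 to 53.0) and 42.4-fold (38.2 to 47.3) higher. The eosinophil granule genes Epx and Prg2 were 71.4-fold (46.1 to 117) and 50.8-fold (40.4 to 64.7) higher. The basophil proteases Prss34 and Mcpt8 were 68.8-fold (57.6 to 82.8) and 53.3-fold (41.3 to 70.0) higher, and Cpa3, a mast cell and basophil carboxypeptidase, was 45.3-fold (32.8 to 64.6) higher. Ms4a3, a gene of committed granulocyte and monocyte progenitors, was 54.4-fold higher, Cd34, a stem and progenitor surface protein, 41.8-fold, and the adhesion receptor Adgrl4 48.7-fold. Igll1, the surrogate light chain of B cell precursors, had 444 reads in bone marrow and 1 read in spleen, a ratio of 399 with an interval of 71.3 to 15804.

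The 12 genes with the largest ratios towards spleen included genes of mature B cells and dendritic cells. Cr2, the complement receptor of follicular and marginal zone B cells, was at 318 CPM in spleen and 1.38 CPM in bone marrow, a 230-fold difference (134 to 433). Fcer2a, the low-affinity IgE receptor of B cells, was 71.1-fold higher in spleen (52.4 to 98.8), and Cxcr5, the follicle-homing chemokine receptor, 48.4-fold (35.0 to 69.0). Fcmr, the IgM Fc receptor, was 33.5-fold higher and H2-Eb2, an MHC class II beta chain, 44.5-fold. Fscn1, an actin-bundling protein of mature dendritic cells, was 42.4-fold higher in spleen. Dtx1, a Notch-pathway ubiquitin ligase, was 41.8-fold higher and Rasgrp3, a Ras exchange factor of B cells, 52.2-fold higher. Adam23, Apol7c, Ryr3 and Il9r were 221-fold, 235-fold, 209-fold and 66.7-fold higher, with 6, 4, 2 and 7 reads in bone marrow.

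**Figure D2:**
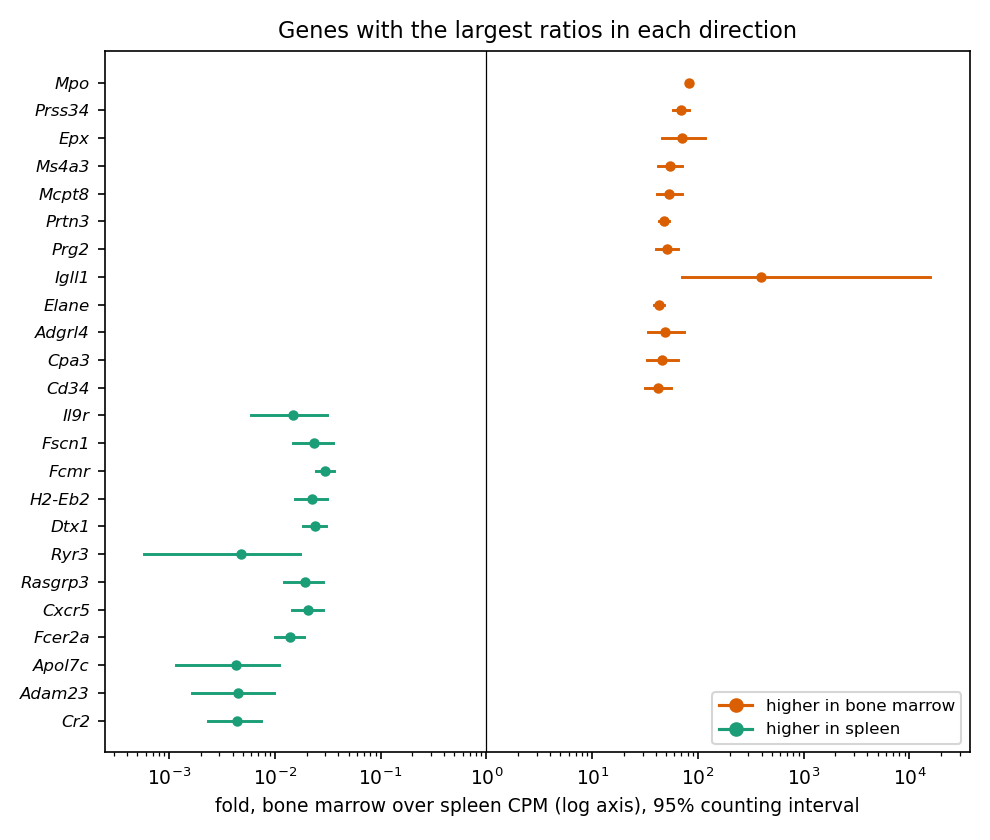
Fold of CPM in the bone marrow library over the spleen library (x axis, log scale) for the 12 genes with the largest log2 ratio in each direction. Points are folds and lines 95% counting intervals. Igll1 has the widest interval, from 71.3 to 15804, because of its single read in spleen.

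Macrophage identity genes were detected in both libraries and divided between them. Of 24 such genes, 5 were higher in bone marrow, 7 were higher in spleen and 12 lay within 2-fold, with a median log2 ratio of 0.04, at the 47.9th percentile of random lists, and a mean of -0.01. The median was -0.02 with library totals alone. Itgam, the CD11b integrin also carried by granulocytes, was at 635 CPM in bone marrow and 156 CPM in spleen, and Lyz2, the lysozyme of myeloid cells, at 1982 and 509 CPM. Cd63, a tetraspanin of lysosomes and granules, was 14.9-fold higher in bone marrow, and Fcgr3 was at 129 and 31.8 CPM. The NADPH oxidase subunit Cybb was at 1319 and 465 CPM. Granulocytes also express these genes, and granulocyte markers were higher in the same library, with a median log2 ratio of 3.97. In the opposite direction, Adgre1, which encodes F4/80, was at 53.1 CPM in bone marrow and 142 CPM in spleen, a 2.68-fold difference (2.42 to 2.98). Mertk, an efferocytosis receptor, was 6.70-fold higher in spleen (4.74 to 9.71). Csf1r, the receptor for macrophage colony-stimulating factor, and Cd68 were 1.85-fold and 1.96-fold higher in spleen, within the 2-fold limit, which Cd68 crossed with library totals alone (-1.02 on the log2 scale).

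Genes of tissue-resident macrophages were more often higher in spleen. Among 15 measured marginal zone and resident macrophage genes, 8 were higher in spleen and 0 in bone marrow, with a median log2 ratio of -1.11, at percentile 0.03. Of the 21 listed genes, 6 were not measured. That median is the ratio of Clec1b, which had 13 reads in bone marrow and 35 in spleen. With a floor of 10 CPM the median was -1.16. A set of 9 core macrophage genes from the identity list moved the same way, with a median of -1.13. Cd5l, a secreted scavenger-receptor protein of resident macrophages, was at 71.8 CPM in spleen and 8.51 CPM in bone marrow, and Marco, a scavenger receptor, had 94 reads in spleen and 1 in bone marrow. The transcription factors Maf and Id3, which lymphocytes also express, were at 54.2 and 36.9 CPM in spleen and at 14.6 and 10.2 CPM in bone marrow. Spic, which specifies red pulp macrophages, was 9.21-fold higher in spleen (6.59 to 13.2), Vcam1 1.90-fold higher, and Siglec1 was nearly equal at 19.3 and 18.6 CPM. The red pulp and heme-iron list had 8 members higher in spleen and 5 higher in bone marrow among 25. Those 5 included Lcn2 and Hp, which neutrophils store in granules, at 2627 and 813 CPM in bone marrow and 139 and 59.2 CPM in spleen, and Tfr2 at 61.5 and 6.03 CPM. The median of the red pulp and heme-iron list was -0.51, at percentile 0.47, and -0.32 with a pseudocount of 5. Monocyte genes had 9 of 23 members higher in bone marrow and 5 higher in spleen (median 0.32, percentile 93.4). That median was 0.07 without members that also mark other cell types and 0.83 with a floor of 10 CPM. Granulocyte lineage cells also express several of the 9, such as Ms4a3, Chil3 and Hp, and granulocyte markers were higher in the same library (median 3.97). Ly6c2 was at 206 and 72.0 CPM and Ccr2, the receptor for monocyte egress from marrow, at 135 and 67.4 CPM. The osteoclast list had 4 of 11 members higher in spleen and 2 in bone marrow (median -0.03, percentile 43.3, and -0.64 with the deposited RPKM), with Acp5 at 201 CPM in spleen and 36.4 in bone marrow.

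Markers of granulocytes, megakaryocytes and progenitors were higher in bone marrow. Of 26 neutrophil and granulocyte precursor genes, 24 were higher in bone marrow and 0 in spleen, with a median log2 ratio of 3.97, above all 10000 random lists. Together these 26 genes took 4.94% of bone marrow reads and 0.251% of spleen reads, against 0.62% and 0.403% for the 24 macrophage identity genes. Those 24 include Lyz2 and Cybb, which granulocytes also express, with 18643 and 12407 reads in bone marrow and 4303 and 3933 in spleen. Their share therefore does not measure macrophage content. S100a8 was at 5635 CPM in bone marrow and 310 CPM in spleen, and Fcnb, a ficolin of granulocyte precursors, at 508 and 14.9 CPM. Eosinophil, basophil and mast cell genes had 13 of 17 members higher in bone marrow and 3 in spleen, megakaryocyte and platelet genes 12 of 17 and 2, and stem, progenitor and MLL-AF9-associated genes 22 of 34 and 3. The medians of those lists were 3.54, 1.95 and 2.33, each above all 10000 random lists. The first was 4.61 with a pseudocount of 0.1 and 4.42 with a floor of 10 CPM, and the others were 1.09 and 1.69 with a pseudocount of 5. Itga2b, the platelet integrin, was at 217 CPM in bone marrow and 11.2 in spleen. Hoxa9 and Meis1, transcription factors that MLL fusions activate and that normal progenitors also express, were 7.35-fold (4.95 to 11.3) and 8.30-fold (6.23 to 11.3) higher in bone marrow, and Kit was 1.87-fold higher. The stromal, osteolineage and endothelial list had 7 of 14 members higher in bone marrow and 2 in spleen (median 0.999, percentile 99.8, but medians of 0.13 with no floor and 0.40 with a pseudocount of 5), at low levels such as 32.5 and 2.01 CPM for Pdgfrb. Cxcl12, a niche chemokine of stromal cells, had 30 reads in bone marrow and 0 in spleen, and the exact interval of its fold began at 6.87.

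Lymphocyte and dendritic cell markers were higher in spleen. All 23 measured T cell genes were higher in spleen by at least 2-fold, with a median log2 ratio of -2.99, below all 10000 random lists. Cd4 was at 221 CPM in spleen and 18.7 CPM in bone marrow, Cd8b1 at 109 and 7.65 CPM, Tcf7 at 361 and 33.3 CPM, and Foxp3, the regulator of regulatory T cells, at 21.3 and 1.06 CPM. Of 22 B cell genes, 15 were higher in spleen and 6 in bone marrow (median -2.42, percentile 0). Cd79a, a chain of the B cell receptor, was at 867 CPM in spleen and 119 in bone marrow, and Cd22 at 807 and 47.8 CPM. Plasma cell genes had 7 of 8 members higher in spleen, with Jchain at 1688 CPM against 228, and their median was -1.73. Conventional dendritic cell genes had 17 of 20 members higher in spleen and 0 in bone marrow (median -2.61, percentile 0, and -1.88 with a pseudocount of 5), with Ccr7 at 264 CPM against 8.29 and Cd83 at 191 against 13.1. NK cell genes had 6 of 16 higher in spleen and 1 in bone marrow (median -0.49, percentile 1.71), and Gzma was at 85.5 and 18.8 CPM. Plasmacytoid dendritic cell genes (median -0.20, percentile 21.5) and erythroid genes (median -0.05, percentile 42.8) lay within the middle of random lists.

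Antigen presentation genes were higher in spleen, as the lymphocyte and dendritic cell markers were. All 15 MHC class II and antigen presentation genes were at least 2-fold higher in spleen, with a median log2 ratio of -2.96, below all 10000 random lists. H2-Aa was at 2713 CPM in spleen and 348 in bone marrow, and Ciita, the master activator of class II genes, was 14.9-fold higher (13.2 to 16.8). H2-DMb2 and H2-Ob, chains of proteins that regulate class II peptide loading and are prominent in B cells, were at 161 and 597 CPM in spleen against 4.89 and 39.8 CPM. MHC class I presentation genes had 8 of 19 members higher in spleen and 0 in bone marrow, with a median of -0.88 at percentile 0.01. H2-K1 was at 2571 CPM in spleen and 1135 in bone marrow.

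Genes used to grade macrophages as M1-like (inflammatory) were higher in spleen more often than in bone marrow. Of 26 M1-associated genes, 15 were higher in spleen, 4 in bone marrow and 7 lay within 2-fold (median -1.25, percentile 0). The largest ratios belonged to Ccr7, Cd40, Cd86 and Gpr18, which B cells and dendritic cells also express: Cd40 was at 67.5 CPM in spleen and 4.57 in bone marrow, and Cd86 at 59.7 and 5.95 CPM. Irf1, an interferon-induced transcription factor, was at 262 CPM in spleen and 105 CPM in bone marrow. Il1b, which encodes interleukin-1 beta, was 4.60-fold higher in spleen (3.85 to 5.51), and Tnf 1.31-fold higher (1.09 to 1.59). Nos2, the inducible nitric oxide synthase, had 2 reads in bone marrow and 0 in spleen, so no difference was detectable at this depth. T cell, B cell and dendritic cell markers were higher in the same library, with median log2 ratios of -2.99, -2.42 and -2.61.

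Genes used to grade macrophages as M2-like (alternatively activated) went both ways. Of 25 measured, 9 were higher in spleen, 6 in bone marrow and 10 lay within 2-fold, with a median of -0.56 at percentile 0.51. T cell, B cell and conventional dendritic cell markers were higher in spleen too (medians -2.99, -2.42 and -2.61). Mrc1, the mannose receptor, was 2.59-fold higher in spleen (2.23 to 3.02), and Tgm2, a transglutaminase, was at 226 CPM in spleen and 28.4 in bone marrow. Chil3, a chitinase-like protein that granulocyte precursors also make, was 16.8-fold higher in bone marrow (15.8 to 17.9), in the library where neutrophil genes were higher. Vegfa was 9.12-fold higher in bone marrow (6.83 to 12.4) and Mgl2 was at 19.2 CPM there and 2.36 CPM in spleen. Cd163 was at 19.0 CPM in spleen and 13.1 in bone marrow. Arg1 had 3 reads in bone marrow and 2 in spleen and Retnla had none in either, so they could not be compared at this depth. Il10, whose log2 ratio is the median of the list, had 9 and 16 reads, a 1.98-fold difference towards spleen with an interval of 0.823 to 5.08 that included equal levels.

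Interferon and NF-kB response genes were higher in spleen as groups. Of 41 interferon-stimulated genes, 25 were higher in spleen and 0 in bone marrow, with a median of -1.13, below all 10000 random lists. Zbp1, a nucleic acid sensor, was at 82.5 CPM in spleen and 21.9 in bone marrow, Slfn5 at 168 and 45.4 CPM, Ifit3 at 26.1 and 6.38 CPM, and Sp100 at 323 and 138 CPM. Irf7, a master regulator of type I interferon responses, was 2.01-fold higher in spleen (1.83 to 2.22), which is -0.999 on the log2(CPM + 1) scale and just inside the 2-fold limit. Interferon receptors and nucleic acid sensors had 9 of 18 members higher in spleen and 1 in bone marrow (median -1.07, percentile 0), including the endosomal receptors Tlr9 at 128 and 22.3 CPM and Tlr7 at 98.0 and 25.4 CPM. TNF and NF-kB response genes had 11 of 23 members higher in spleen and 3 in bone marrow (median -0.996, percentile 0), with Relb at 197 and 14.9 CPM and Traf1 at 185 and 13.7 CPM. Pattern recognition receptors had 14 of 31 members higher in spleen and 6 in bone marrow (median -0.73, percentile 0), with Tlr1 at 148 CPM in spleen and 11.2 in bone marrow, and Clec5a, a C-type lectin of immature myeloid cells, at 129 CPM in bone marrow and 5.91 in spleen. B cells, T cells and dendritic cells also express many of these genes, and their markers were higher in the same library. JNK and MAPK signalling genes (median -0.23, percentile 6.45) did not stand apart, although Map3k1 was at 297 CPM in spleen and 83.0 in bone marrow and Jun at 265 and 611 CPM.

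Immune checkpoint and suppression genes had 8 of 19 members higher in spleen and 1 in bone marrow (median -0.59, percentile 0.77, but a median of -0.16 with no floor). Havcr2, which encodes TIM-3, was at 72.0 CPM in spleen and 8.61 in bone marrow, Pdcd1lg2 at 21.8 and 4.36 CPM, and Hmox1, heme oxygenase 1, at 224 and 62.0 CPM. Chemokine receptors had 8 of 17 members higher in spleen and 2 in bone marrow (median -0.87, percentile 0.09), led by the lymphocyte receptors Cxcr5, Ccr7 and Ccr6. Lymphocytes or dendritic cells also express many members of both lists, and T cell, B cell and conventional dendritic cell markers were higher in the same library (medians -2.99, -2.42 and -2.61). Chemokines had 5 of 14 members higher in bone marrow and 4 in spleen (median 0.11, percentile 63.8), with Ccl5 at 229 CPM in spleen and 109 in bone marrow and Ccl9 at 92.5 CPM in bone marrow and 24.1 in spleen. Complement genes had 7 of 17 members higher in spleen and 5 in bone marrow (median -0.69, percentile 0.675, but medians of 0.28 with no floor on low genes and -1.13 with a floor of 10 CPM), with C3 at 1361 CPM in bone marrow and 108 in spleen and Cd55 at 194 CPM in spleen and 16.8 in bone marrow. Growth factors, angiogenic factors and cytokines had 11 of 28 members higher in bone marrow and 5 in spleen (median 0.35, percentile 96.1), and the median ran from 0.21 with a pseudocount of 5 to 0.89 with a floor of 10 CPM. Angpt1, an angiopoietin that progenitors and megakaryocytes also express, was at 116 CPM in bone marrow and 5.79 in spleen, Hgf at 24.7 and 2.84 CPM, and Tgfb1 at 355 and 273 CPM.

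Proliferation and glycolysis genes were higher in bone marrow. All 30 G2/M genes and 27 of 28 G1/S genes were at least 2-fold higher there, with medians of 2.05 and 1.87, each above all 10000 random lists. Mki67 was 2.85-fold higher in bone marrow (2.72 to 2.98), Top2a was at 862 CPM there and 192 in spleen, and the replication helicase gene Mcm6 at 581 and 164 CPM. Progenitor and granulocyte precursor markers were higher in the same library, with median log2 ratios of 2.33 and 3.97. Hypoxia and glycolysis genes had 18 of 28 members higher in bone marrow and 2 in spleen (median 1.13, percentile 100), with Hk3, a hexokinase of myeloid cells, at 463 and 54.2 CPM, Gpi1 at 1634 and 472 CPM and Pkm at 1649 and 569 CPM. All 36 nuclear-encoded oxidative phosphorylation genes stayed within 2-fold, but their median of 0.56 lay at percentile 99.98, with Uqcrc1 at 283 CPM in bone marrow and 155 in spleen. For the glycolysis and oxidative phosphorylation lists too, progenitor and granulocyte precursor markers were higher in the same library. Whether such cells carried these transcripts was not tested.

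**Figure D3:**
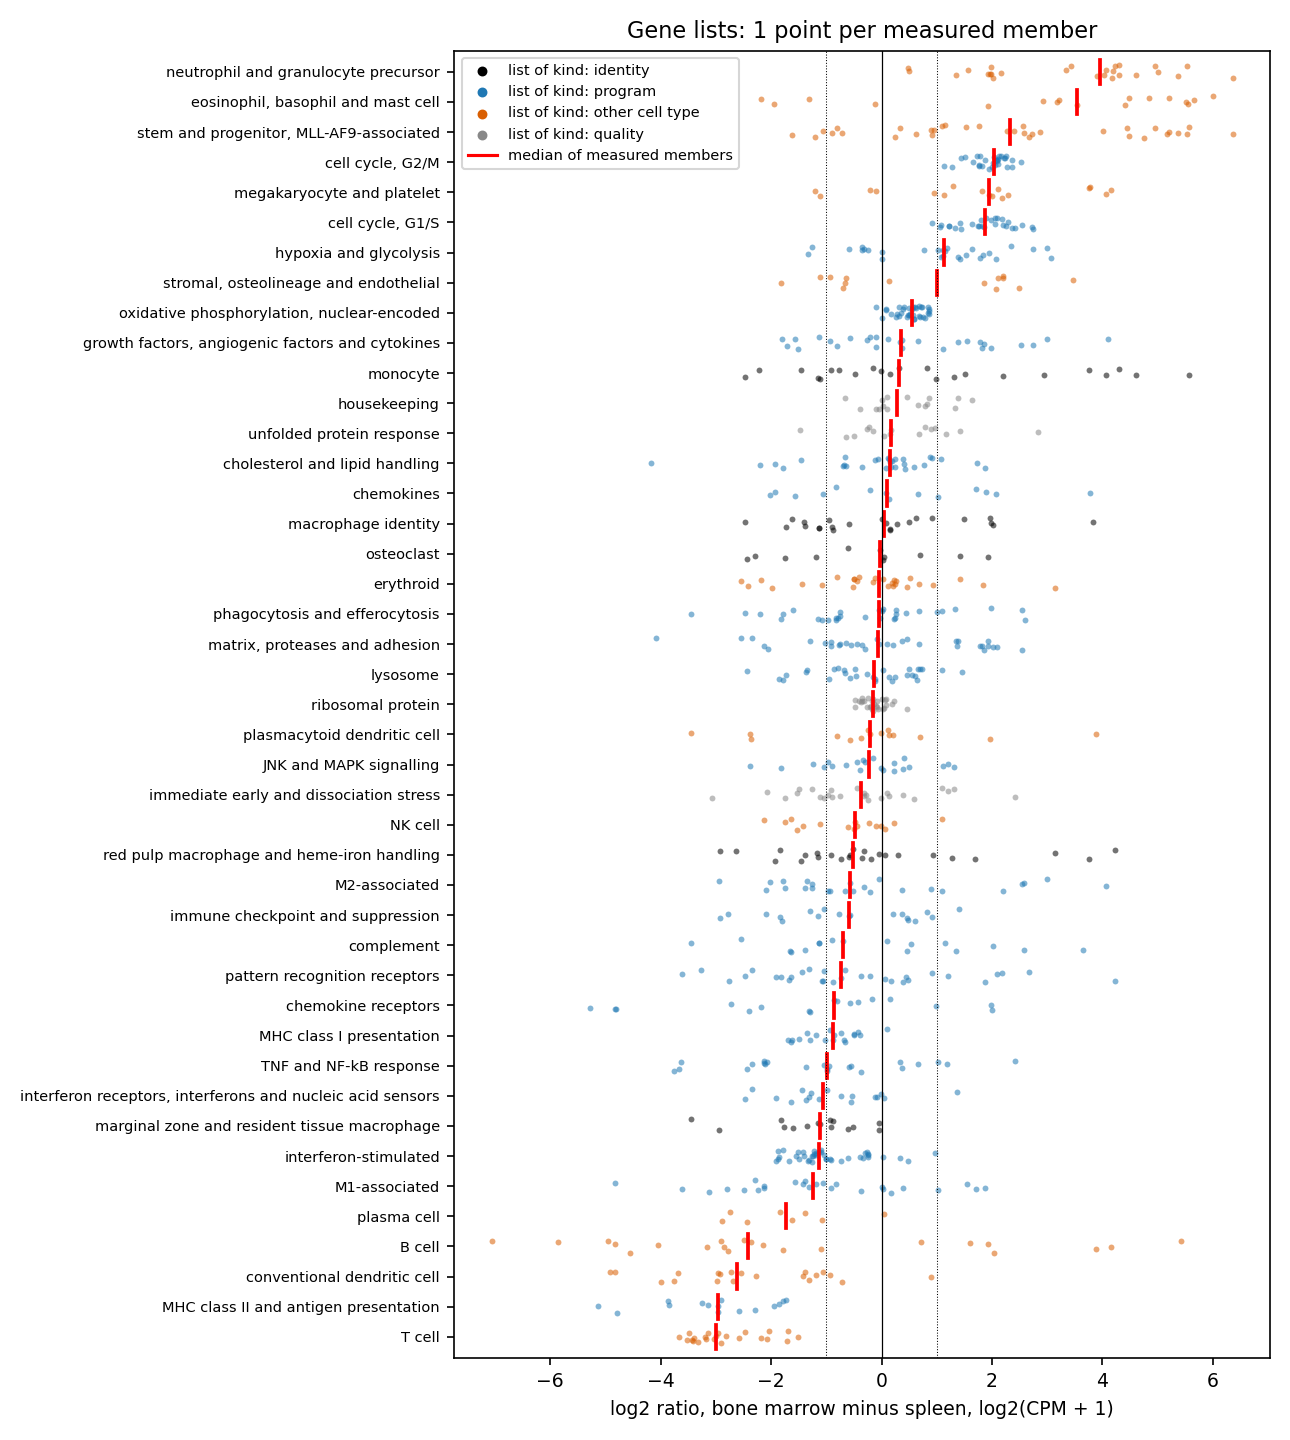
Log2 ratio, bone marrow minus spleen, on log2(CPM + 1) for each measured member of the 43 gene lists (points, coloured by kind of list), with the median of each list as a red bar and dotted lines at a 2-fold difference. Lists run from T cell genes (median -2.99) at the bottom to neutrophil genes (median 3.97) at the top.

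Most other programs lay within the central 95% of random lists. Lysosome genes (median -0.14, percentile 10.7), phagocytosis and efferocytosis genes (median -0.05, percentile 34.4), cholesterol and lipid genes (median 0.15, mean -0.15, percentile 70.8) and matrix, protease and adhesion genes (median -0.06, mean 0.02, percentile 27.1) held members on both sides. Scd1, a stearoyl-CoA desaturase, was 18.7-fold higher in spleen (16.6 to 21.2), Acp5 5.53-fold higher, and Mmp12, the macrophage elastase, was at 23.2 CPM in spleen and 0.425 in bone marrow. All 29 ribosomal protein genes stayed within 2-fold (median -0.15, percentile 8.21). Immediate early and dissociation stress genes lay outside that range, with 8 of 26 members higher in spleen, 4 in bone marrow and a median of -0.38 at percentile 1.93, with Klf2, which lymphocytes also express, at 423 CPM in spleen and 99.4 in bone marrow, and unfolded protein response genes a median of 0.16, at percentile 73.8. Housekeeping genes had a median of 0.28, at percentile 86.6. Actb was at 4560 CPM in spleen and 3464 in bone marrow, and Pgk1 at 185 and 582 CPM. In all, 9 lists lay above the central 95% of random lists, 19 below it and 15 within it.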

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

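No paired analysis was possible because each tissue had 1 library, and for the same reason no library could be left out. The main counts were 1832 genes higher in bone marrow and 1898 in spleen. They came to 573 and 530 under a 4-fold rule, and with a pseudocount of 5 the spleen count was 1210 and the bone marrow count 1244. Under the other alternatives they ranged from 1381 to 2090 for bone marrow and from 1342 to 2237 for spleen. Leaving out markers of other cell types, an alternative chosen after seeing the data, gave 1750 and 1813. None of the 200 named genes at least 2-fold apart changed direction under any alternative run. Floors and pseudocounts cannot change a direction, and the scaling shifts were small beside 2-fold, so this is no check of those genes. Of 245 named genes past the floor, 78 moved beyond their counting interval with a pseudocount of 5, 53 with the deposited RPKM and 35 with library totals. Of the lists outside the central 95% of random lists, the complement list alone changed sign, to a median of 0.28 with no floor, where barely read genes enter. The T cell median was -2.45 with a pseudocount of 5, and the erythroid median was 0.24 with a floor of 10 CPM. The M1-associated median was -1.18 and the M2-associated median -0.56 without members that also stand in a list of another cell type. That left out only 1 and 4 members. Genes that B cells and dendritic cells also express, such as Cd40 and Cd86, stayed in, so this is a weak check. Irf7, at -0.999, crossed the 2-fold limit with library totals alone (-1.06), the deposited RPKM (-1.06), a pseudocount of 0.1 (-1.01) and, chosen after seeing the data, TMM factors without other cell type genes (-1.06). Cd68 crossed it with library totals (-1.02), the deposited RPKM (-1.02) and those TMM factors (-1.02), and Ccr2 with DESeq2 size factors and a pseudocount of 0.1. Scaling moved the median of all genes between -0.04 and 0.04. Depth limits genes near the floor of 10 reads and leaves the direction of Nos2, Arg1, Retnla and Il10 open. Depth does not replace the missing replicates.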

Other observations

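The tests of maturation stages, of scaling, of the macrophage share and of the myeloid-restricted M1-associated genes were chosen after the results were seen. The second lists of granulocyte, B cell and T cell genes were written after the first lists had been read but before their own values were seen.

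Genes that mark successive stages of granulocyte and B cell development differed in their ratios. A set of 6 early granulocyte genes (Mpo, Elane, Prtn3, Ctsg, Ms4a3 and Prss57) ran from 4.95 to 6.36 on the log2 scale, 6 specific granule genes (Ltf, Camp, Ngp, Lcn2, Cd177 and Chil3) from 3.91 to 4.30, and 8 genes of mature neutrophils, such as Cxcr2, Csf3r, Mmp9 and Retnlg, from -1.05 to 2.10. The early and mature sets differed by 3.50 in their medians. Of the B cell list, the 6 members at least 2-fold higher in bone marrow were Igll1, Vpreb1, Vpreb2, Dntt, Rag1 and Rag2, all genes of B cell precursors, with Dntt at 64.7 and 3.43 CPM. Their median exceeded that of the 6 members with the largest ratios towards spleen (Cr2, Fcer2a, Ms4a1, Cd22, Bank1 and Fcmr) by 7.86. Both differences compare genes picked after their values were seen, so they do not bear on whether younger cells stood behind the bone marrow library, which stays open.

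Further genes were picked after their values were seen. Hlf, a transcription factor of stem cells, was at 53.7 CPM in bone marrow and 0.828 in spleen, Erg at 79.9 and 2.72 CPM, Prom1 at 128 and 3.90 CPM, Gata2 at 244 and 9.93 CPM, and Tie1, an endothelial and stem cell receptor, at 30.6 and 0.709 CPM. In the opposite direction, Lta, a lymphotoxin of lymphocytes, had 201 reads in spleen and 3 in bone marrow, and Ptprc, the pan-leukocyte CD45, was 3.35-fold higher in spleen. Xist was present in both libraries at 7231 and 10299 reads, while the Y-linked genes Ddx3y and Uty had 0 reads in bone marrow and 1 and 2 reads in spleen.

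The pattern that stands out most is the level of granulocyte genes in the bone marrow library. A factor per library shifts all genes alike. The list's median exceeded the median of all measured genes by 3.94 (interval over the list's genes 1.96 to 4.27). Scaling alone therefore does not account for that level. A lower macrophage share in the bone marrow library stays open. T cell markers were lower there, with a median of -2.99. That cannot exclude a lower share, because the cells sorted beside macrophages can differ between the tissues. A set of 9 core macrophage genes from the identity list, Adgre1 and Mertk included, had a median of -1.13 (interval -1.41 to -0.89). Of these 9, 8 were higher in spleen, counting differences of any size. RNA from granulocyte precursors is a candidate explanation. A second list of 23 granulocyte genes, none in another list used here, had a median of 2.53 (95% order-statistic interval 1.72 to 3.11). Of its members, 21 were higher in bone marrow. S100a9, Ngp and Mpo stood at 8965, 8892 and 8543 CPM where Adgre1 stood at 53.1 and Csf1r at 197. Levels of different genes do not measure shares of cells. Of the 26 genes in the first list, 4 also stand in a macrophage or monocyte list, a sort on Itgam would not remove granulocytes, the gate is not given in the sources used here, and expression by marrow macrophages or leukaemia cells themselves was not tested.

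The counterpart in the spleen library is the level of lymphocyte genes, of whose first lists 2 B cell and 0 T cell members stand in another list. Second lists of 17 B cell genes and 22 T cell genes, none in another list used here, had medians of -1.86 (interval -2.47 to -1.45) and -1.98 (interval -2.28 to -1.51). These values go with RNA from B cells and T cells in the spleen library, where Cd79a and Cd4 reached 867 and 221 CPM. Among macrophage genes there, Adgre1 stood at 142 CPM and Csf1r at 364 CPM, and such levels do not measure shares of cells. A gate on lymphocyte markers would remove such cells, and none is given in the sources used here. RNA taken up with engulfed lymphocytes, and a biological difference between marrow and spleen macrophages, were not tested and stay open.

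The higher M1-associated genes in spleen bear on how marrow and spleen macrophages would be graded. The test held that, if lymphocytes and dendritic cells carried those transcripts, members with myeloid-restricted expression should not be higher in spleen. Dendritic cells are myeloid too and can express such members, so the test could not separate them from macrophages. The 10 measured members chosen as such went both ways, 5 in each direction, with a median of -0.41 and an interval of -1.57 to 1.55, from Il1b at -2.14 to Fpr2 at 1.88. Whether other cells carried the transcripts cannot be told apart from expression by macrophages. Myeloid-restricted members do not set dendritic cells apart, and the members are few and divided.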
